A study of Bos taurus and Cervus elaphus with 24 samples.

How the data were processed

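RNA from blood labelled as peripheral blood nuclear cells was measured on 24 Agilent bovine oligonucleotide arrays with probes for genes across the genome. Blood was drawn into tubes that fix RNA at collection, and total RNA came from the matching kit. The Cy5 dye carried the animal's RNA and the Cy3 dye a reference pooled from 20 cattle outside the study groups, in the same orientation on all 24 arrays. The labels give 6 groups of 4 arrays: Holstein-Friesian cattle (HF), Polish Red cattle (PR) and deer, each in the dry period and at peak lactation. Per the series text, the same 4 animals of each breed or species were bled in both states, and the subject numbers in the labels were read as those animals.

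Per the file headers, the spot files hold the intensity of each spot, as mean brightness and local background in both channels, together with processed signals that Agilent Feature Extraction had detrended and dye-normalized. Per the file headers, the log ratio column is the log10 of the processed Cy5 signal over the processed Cy3 signal. Per the file headers, other columns are yes-or-no calls per spot for signal above background, saturation and uneven spots. The processing notes name Feature Extraction 10.7.3.1 and the file headers name 10.10.1.1. The authors' 3 deposited tables hold normalized log2 ratios for 437 probes in HF, 158 in PR and 576 in deer that they had selected by an analysis of variance with Tukey's test in GeneSpring. Each deposited log2 value is centred near its probe's median over the arrays. The steps of that normalization are not stated.

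The mean spot signal was corrected by normexp with an offset of 50 against the median local background in both channels. The log2 ratio of Cy5 over Cy3 was then adjusted by loess within each array, without the 1417 control spots, and spots of one probe were averaged. These steps used limma 3.58.1 with statmod 1.5.0 in R 4.3.3, and files were read by data.table in version 1.17.8. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The files pair 33096 of the 43653 probes with a gene name after lookup in the reference tables, giving 15772 names. The headers place the probes on the UMD 3.1 cattle assembly. The reference annotation is on another assembly, so coordinates come from the files alone, and exon or untranslated region assignments were not made.

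A probe was tested where its Cy5 signal was well above background on at least 3 of the 4 arrays of at least 1 group in the contrast. The linear model of limma had 6 group means over all 24 arrays, and adjusted p-values are Benjamini-Hochberg values over the probes tested, with a threshold of 0.05. The contrasts were peak lactation minus dry period in each of HF, PR and deer, the difference of the HF and PR effects, the difference of the deer effect from the mean cattle effect, HF minus PR in each state, and deer minus the mean of both breeds in each state. The study's text describes an analysis of variance without pairing, so the model has no animal term and a model with an animal block was run beside it. As a check of the subject numbers, each animal's arrays from both states were correlated after group means were removed, across probes. The own correlation was over 0.1 in 4 of 4 HF, 2 of 4 PR and 4 of 4 deer, although HF arrays of the same animal also shared a slide. It was the highest among the possible partners in 4 HF, 3 PR and 4 deer animals.

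Before the data were examined, 30 gene lists were fixed. They cover interferon-stimulated, neutrophil and granule, monocyte, T cell, gamma delta T cell, B cell, NK and cytotoxic cell, eosinophil, basophil and mast cell, platelet and megakaryocyte, erythroid, MHC class II and MHC class I and peptide loading genes. They also cover cytokine, chemokine and NF-kappaB, pattern recognition receptor, acute phase and antimicrobial peptide, complement and phagocyte receptor, milk protein and mammary, prolactin, growth hormone and IGF axis, glucocorticoid and steroid response, and vitamin D and calcium handling genes. The rest are fatty acid oxidation and PPAR target, cholesterol synthesis, glycolysis, mitochondrial respiratory chain, cytosolic ribosomal protein, cell cycle, antioxidant, heat shock and chaperone, immediate early and circadian clock genes. Neutrophil and acute phase lists share 13 genes. In the milk protein list GPAT4 also stands under its old symbol AGPAT6, so it can count as 2 members. Each gene was represented by the probe with the highest mean intensity. Lists were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the 30 lists. The same lists were tested with an estimated correlation, with fry, and with the animal block. With the preset correlation, other splits of the same 8 arrays gave a median of 12 lists in HF, 5.5 in PR and 6 in deer. A list's mean per array was also compared between states by an exact two-sided permutation test over the splits of 8 arrays, whose smallest possible p is 0.0286, and by flipping the signs of the 4 animals' differences, whose smallest possible p is 0.125.

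The rule for named genes was fixed before the data were examined. For each state contrast it takes up to 12 genes per direction with the largest change among those past the threshold, filled up to 8 with the smallest unadjusted p. Genes without a characterised name are left out of it. For each list it allows up to 4 members with the smallest unadjusted p, of which 3 were taken for lists past the threshold, or 2 where 1 of them is not reported here. For the differences of effects and for HF against PR it takes up to 6 genes per direction past the threshold, or 3 where none passes. For genes seen above background in 1 state only it takes up to 3 genes, with a bound from the Cy5 signal alone after loess and Aquantile, which is open to dye bias. For deer against cattle no gene is ranked, since deer RNA meets cattle probes and a difference of level mixes expression with sequence mismatch. The 5 probes past the threshold in the state contrasts and further erythroid genes of the deer are named in addition, after their values were seen.

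Alternatives fixed before the data were examined were the processed signals, median centring, between-array scaling by 2 methods, the Cy5 channel alone, other background filters, only the groups of a contrast, animal or slide blocks, array position, a trended robust variance, array weights, 1 probe per gene, the authors' kind of test, other list tests and leaving out each array. Chosen after seeing the data were the models without PR dry replicate 1, without deer lactation replicate 2 and without the 4 arrays of slides G and H, for contrasts that do not hold those arrays as well. Tested on simulated data with the real arrays' spread, limma recovered 89% of 100 probes changed by 1 on the log2 scale in HF among 33101 probes, 92% in PR among 32590 and 92% in deer among 33389. For the difference of the HF and PR effects it recovered 73% among 32213 probes. The HF, PR and deer simulations also held 100 probes changed by 2, and gave 9, 7 and 7 false calls. Their noise was independent between genes and arrays, without animal or slide effects. With so many changed probes, the Benjamini-Hochberg threshold was also easier to reach than in the real state contrasts, which called 3, 0 and 2 probes. For both reasons recovery in the real data may be lower. The number of arrays limits the precision. The arrays of the 10 slides were lettered A to J, with 4 positions each. HF animals have both states on 1 slide. Deer have dry and lactation arrays together on slide J alone, and 3 of 4 PR dry arrays share no slide with HF.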

Results

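Gene expression in blood was compared between the dry period, the rest before birth when no milk is made, and peak lactation, the time of highest milk output, in cattle of 2 breeds and in deer. Holstein-Friesian is a high-yielding dairy breed and Polish Red a local breed of lower yield. The design asks which transcripts in blood differ between the states within each breed or species, and the labels also allow breeds and species to be set side by side. Each of the 6 groups holds 4 arrays, and each value is the log2 ratio of an animal's RNA to the common cattle reference. In 23 of the 24 arrays the median Cy5 spot intensity lay between 109 and 255, and 30835 to 39110 of 43653 probes were well above background. PR dry replicate 1 stood apart, with a median Cy5 intensity of 2038, 43635 probes above background and 703 outlier spots against at most 75 on any other array. The correlation of spike-in controls in the file headers was 0.17 to 0.40 on the arrays of HF animals 2 and 3, on slides G and H, and 0.33 on PR dry replicate 1, against 0.899 or more on all others. Log2 ratios spread less on deer lactation replicates 2 and 4 (SD 0.52 and 0.66) than on the other deer arrays (0.80 to 0.85). Across probes, correlations between arrays ran from 0.87 to 0.97 among deer, from -0.24 to 0.68 among cattle, and from -0.05 to 0.27 between deer and cattle.

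In HF, NR1H3 rose at peak lactation. It encodes liver X receptor alpha, a nuclear receptor that senses oxidised cholesterol in macrophages and other cells. All 3 of its probes passed in limma, and they were the only probes of the 33101 tested to do so. The probe with the brightest signal lies on chromosome 15 at 78330145 to 78330204 (UMD 3.1). Its log2 ratio went from -1.12 ± 0.14 to -0.09 ± 0.24 (SD, n = 4 each), a rise of 1.03 (SE 0.13, limma adjusted p = 0.00412) seen in 4 of 4 animals. The other two probes rose by 1.03 (SE 0.15, adjusted p = 0.0207) and 0.56 (SE 0.09, adjusted p = 0.0303). With an animal block these adjusted p-values became 0.0529, 0.0715 and 0.0956, and the 1 probe called in that model was another one. Over 26 alternatives the rise of the brightest probe ran from 0.87 to 1.14, and its call ended in 8 of them. At an unadjusted p under 0.05 there were 2574 probes, and the authors' kind of test, an analysis of variance with Tukey's comparison and no further adjustment, gave 360. On PR arrays the brightest NR1H3 probe lay between -0.95 and -0.30 in the dry period and between -0.30 and -0.25 at peak lactation. The HF and PR effects on it did not differ past the threshold.

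The genes ranked next in HF did not pass, with adjusted p-values of 0.172 or more, and all had the same sign in 4 of 4 animals. On the higher side at peak lactation were MMP9, the gelatinase stored in neutrophil granules, by 1.66 (SE 0.35), and TNFSF9, the ligand of the T cell costimulator 4-1BB, by 1.21 (SE 0.24). OSCAR, an activating receptor of myeloid cells, differed by 1.11 (SE 0.23), ACSL6, an acyl-CoA synthetase, by 0.92 (SE 0.18), and CYRIA, a regulator of actin, by 0.85 (SE 0.17). LTBR, the lymphotoxin beta receptor, differed by 0.78 and IDH1, the cytosolic isocitrate dehydrogenase that makes NADPH, by 0.42. On the lower side were VAMP1, a protein of vesicle fusion, at -0.53 (SE 0.11), and the centrosome protein CNTROB at -0.42 (SE 0.10). CLSTN1 at -0.43, EPHX4 at -0.41, GABBR1 at -0.35, SMIM24 at -0.34, PRR22 at -0.32 and THEM6 at -0.32 completed the ranking. Among genes above background in HF lactation alone, the Cy5 signal of the monocyte-attracting chemokine CCL2 was at least 1.40-fold and that of the adaptor GAB3 at least 1.06-fold higher than in the dry period, while their log2 ratios to the reference differed by 0.31 (adjusted p = 0.929) and 0.082 (adjusted p = 0.927).

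As groups, genes of innate immune cells were higher in HF at peak lactation and genes of lymphocytes lower by camera at its preset correlation, but of 17 lists called only the monocyte list held with an estimated correlation. The largest shift was in neutrophil and granule genes, with 29 of 30 members higher and a median of 0.70 (camera adjusted p = 1.59e-12, and adjusted p = 0.114 with an estimated correlation). Among them MMP9 and the calprotectin subunit S100A9 (1.40, SE 0.40) were the 2 that passed when adjusted over the list alone, and the chemokine receptor CXCR2 had 0.82. Acute phase and antimicrobial peptide genes, which share 13 members with that list, had 26 of 32 higher and a median of 0.64 (adjusted p = 1.87e-09, and adjusted p = 0.114 with an estimated correlation). S100A12 had 1.23 and ORM1, the carrier protein orosomucoid, 0.60, with ORM1 higher in 2 of 4 animals. Monocyte genes had 20 of 23 members higher, a median of 0.44 and an adjusted p = 3.82e-09. They were the only HF list that held, with an adjusted p = 0.00563 with an estimated correlation and 0.00454 by fry. The receptor for lipopolysaccharide TLR4 had 0.76 and FGL2 had 0.68. HF animals 2 and 3 carry much of these shifts. Without their arrays, those of slides G and H, the neutrophil median was 0.18 (adjusted p = 0.0354), the acute phase median 0.079 (adjusted p = 0.279) and the monocyte median 0.28 (adjusted p = 0.000112), with MMP9 at 0.77, S100A9 at 0.64 (SE 0.49) and S100A12 at 0.26. Of 65 values for single genes named in HF, 29 lay nearer to 0 by over 1.5 times without these arrays, and 8 of the 17 list medians did. Without HF lactation replicate 3 alone the neutrophil median was 0.24 and the acute phase median 0.18.

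Immediate early genes, which respond within minutes to stimuli, had 25 of 29 members higher and a median of 0.40 (adjusted p = 2.38e-10, and adjusted p = 0.114 with an estimated correlation). JUN at 1.07, ATF3 at 0.72 and KLF4 at 0.64 were among the 4 that passed when adjusted over the list alone. This rise too rests in part on animals 2 and 3, with a median of 0.15 without their arrays and 0.22 without HF lactation replicate 3, where JUN had 0.65. Interferon-stimulated genes had 41 of 46 higher and a median of 0.29 (adjusted p = 2.97e-08, and adjusted p = 0.246 with an estimated correlation). LGALS9, a galectin, had 0.49, and the antiviral genes IFIT3 and IFIT5 had 0.96 and 0.46, and none passed over the list alone. Pattern recognition receptor genes had 28 of 37 higher, a median of 0.14 and an adjusted p = 1.6e-06 (0.114 with an estimated correlation). The inflammasome sensor NLRC4 passed over the list alone (0.70, SE 0.17), and NOD2 had 0.51 and TLR7 had 0.32. Cytokine, chemokine and NF-kappaB genes had 27 of 37 higher and a median of 0.19 (adjusted p = 1.65e-05, and adjusted p = 0.114 with an estimated correlation). Examples are TNFAIP6 at 1.26, the interleukin-1 antagonist IL1RN at 0.91 and the B cell factor TNFSF13B at 0.54. Without slides G and H the cytokine median was 0.12, TNFAIP6 had 0.38 and IL1RN 0.56. Complement and phagocyte receptor genes had 24 of 30 higher and a median of 0.16 (adjusted p = 3.7e-05, and adjusted p = 0.136 with an estimated correlation). In that list the Fc receptor FCGR3A (1.06, SE 0.27) and properdin, CFP (0.69, SE 0.21), passed over the list alone, and C5AR1 had 0.80.

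On the lymphocyte side, B cell genes had 18 of 23 members lower in HF lactation and a median of -0.29 (adjusted p = 4.13e-05, and adjusted p = 0.246 with an estimated correlation). CD79A, part of the B cell receptor, had -0.64 and HVCN1 had -0.51. NK and cytotoxic cell genes had 22 of 25 lower and a median of -0.24 (adjusted p = 0.000743, and adjusted p = 0.45 with an estimated correlation), with the granule protein granulysin, GNLY, at -1.01, KLRD1 at -0.40 and CST7 at -0.32. T cell genes had 26 of 30 lower and a median of -0.13 (adjusted p = 0.011, and adjusted p = 0.537 with an estimated correlation), with CD6 at -0.46, GATA3 at -0.46 and TESPA1 at -0.28. The T cell call ended without HF lactation replicate 3 (median -0.044, adjusted p = 0.509, GATA3 at -0.22) and without slides G and H (median -0.0895, adjusted p = 0.161), where the B cell median was -0.15 and the NK median -0.31. Gamma delta T cell genes had 6 of 8 lower and a median of -0.33 and missed the threshold (adjusted p = 0.055), although 3 members passed when adjusted over the list alone and the animal block gave an adjusted p = 0.0146.

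Several metabolic and hormonal lists passed as well. Glycolysis genes had 20 of 28 members higher and a median of 0.22 (adjusted p = 3.7e-05, and adjusted p = 0.246 with an estimated correlation). SLC2A6, a glucose transporter, had 0.75, PFKFB4 had 0.42 and GAPDH had 0.30. With array position as a factor the glycolysis median changed sign, to -0.022. Glucocorticoid and steroid response genes had 19 of 27 higher, a median of 0.10 and a mean of 0.32 (adjusted p = 7.82e-05, and adjusted p = 0.197 with an estimated correlation). CXCR4 (1.21) and the kinase SGK1 (1.05) were among those that passed over that list alone. Milk protein and mammary genes had 10 of 17 higher and a median of 0.066 (adjusted p = 0.0212, and adjusted p = 0.128 with an estimated correlation). The examples act in fat metabolism as well as milk: XDH (0.61), the acyltransferase GPAT4 (0.67) and MFGE8 (0.22). Prolactin, growth hormone and IGF axis genes had 22 of 30 higher and a median of 0.065 (adjusted p = 0.0222, and adjusted p = 0.246 with an estimated correlation), with JAK2 at 0.40, STAT5B at 0.33 and IGF1R at 0.31. Antioxidant genes had 25 of 37 higher and a median of 0.089 (adjusted p = 0.0421, and adjusted p = 0.45 with an estimated correlation), with HMOX1 at 0.64, its regulator NFE2L2 at 0.50 and PRDX5 at 0.46. Their median too changed sign with array position as a factor, to -0.032. Cytosolic ribosomal protein genes had 75 of 79 lower and a median of -0.12 (adjusted p = 3.7e-05, and adjusted p = 0.49 with an estimated correlation), with RPS28 at -0.33, RPL23A at -0.27 and RPS16 at -0.21. In that list the Cy3 reference passed in the other direction (mean 0.013, SE 0.030, adjusted p = 0.0285), and Cy5 alone had a mean of -0.061 (SE 0.067) against -0.12 (SE 0.10) for the log2 ratio. Without slides G and H the glucocorticoid (adjusted p = 0.0624), milk protein (0.0776), prolactin axis (0.0749) and antioxidant (0.29) calls ended, and without HF lactation replicate 3 SGK1 had 0.66.

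The other 12 lists did not pass in HF. Their medians were 0.067 for MHC class I and peptide loading genes, 0.066 for heat shock and chaperone genes, 0.038 for erythroid genes, 0.034 for cholesterol synthesis genes, 0.023 for fatty acid oxidation and PPAR target genes and 0.011 for mitochondrial respiratory chain genes. They were -0.030 for cell cycle genes, -0.033 for eosinophil, basophil and mast cell genes, -0.051 for platelet and megakaryocyte genes, -0.074 for vitamin D and calcium handling genes, -0.077 for circadian clock genes and -0.14 for MHC class II genes. Taken per animal, the neutrophil mean rose by 0.11 to 1.47 and the monocyte mean by 0.21 to 0.62 from the dry period to lactation. An exact permutation test of the list means gave p = 0.114 for neutrophil genes and p = 0.0286 for monocyte, cytokine, glucocorticoid and immediate early genes, the smallest p that 4 against 4 arrays allow, and p = 0.156 for each of these 4 after adjustment over 30 lists. That test leaves the pairing of the animals aside. An exact test that flips the signs of the 4 animals' differences gave p = 0.125 for each of these 5 lists, the smallest that 4 animals allow.

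**Figure D1:**
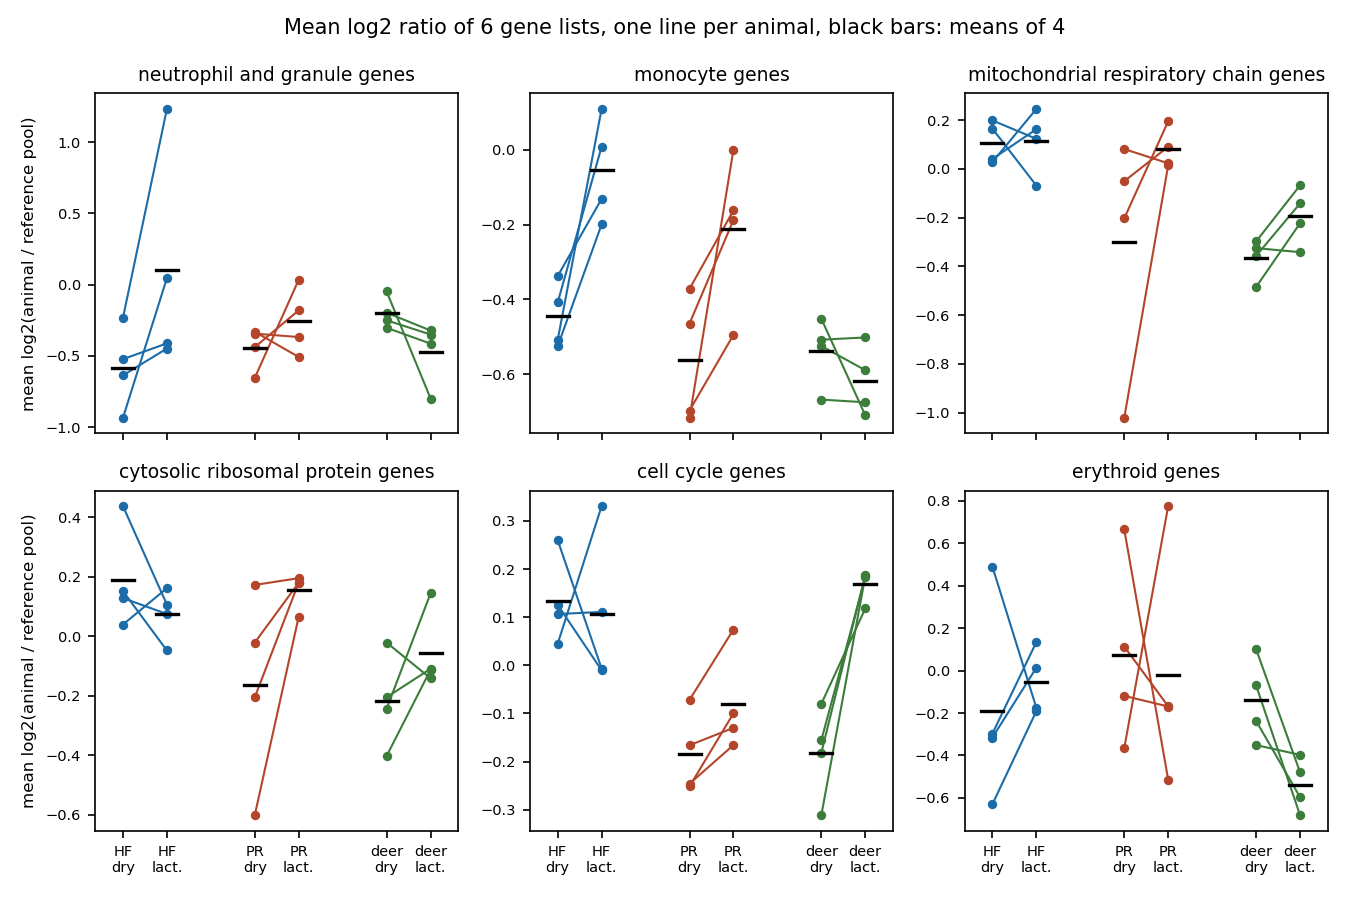
Mean log2 ratio to the common reference of 6 gene lists on each array (vertical axes, log2), with points for arrays joined within an animal from dry period to peak lactation and black bars for the means of 4 arrays. In HF the monocyte mean is higher at peak lactation in 4 of 4 animals, by 0.21 to 0.62, and in deer the cell cycle mean is higher in 4 of 4, by 0.20 to 0.50.

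In PR, no probe passed, and the genes nearest to passing were those that carry fatty acids into mitochondria. CPT1A, which controls entry of long-chain fatty acids, went from -0.95 ± 0.28 to 0.34 ± 0.35 (SD, n = 4 each), 2.46-fold higher (SE 0.24 on the log2 scale, limma adjusted p = 0.521). SLC25A20, the carnitine carrier of the inner membrane, differed by 0.77 (SE 0.15, adjusted p = 0.521), and PDK4, the kinase that restrains glucose oxidation, by 1.19 (SE 0.24, adjusted p = 0.643) with all 8 of its probes higher. These 3 were higher in 4 of 4 animals and passed when adjusted over the fatty acid oxidation list alone (0.000528, 0.000528 and 0.000878). Of 32590 probes tested, limma called 0, against 1861 at an unadjusted p under 0.05, 130 by the analysis of variance with Tukey's comparison and 0 with the animal block. Others on the higher side were FCGRT, the receptor that recycles antibodies, at 0.90, RPL39 at 0.90, KLF10 at 0.79, RPS27 at 0.76 and the zinc transporter SLC30A6 at 0.48. On the lower side were the deacetylase HDAC7 at -0.37, INPP5B at -0.35, ITGA10 at -0.35, VAMP1 at -0.34, LY6G5B at -0.33, PHC1 at -0.30, TAF1 at -0.25 and CAPZB at -0.24. No gene was above background in 1 PR state alone.

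As groups, genes of mitochondrial energy production and of the ribosome were higher in PR at peak lactation by camera at its preset correlation. No PR list held with an estimated correlation. Mitochondrial respiratory chain genes had 76 of 78 members higher and a median of 0.39 (camera adjusted p = 1.59e-19, and adjusted p = 0.427 with an estimated correlation), with COX6C at 0.75, ATP5ME at 0.54 and NDUFB2 at 0.46. Cytosolic ribosomal protein genes had 74 of 79 higher and a median of 0.25 (adjusted p = 1.17e-12, and adjusted p = 0.427 with an estimated correlation), and 7 of them passed when adjusted over the list alone, among them RPL39, RPS27 and RPL31 (0.69). Fatty acid oxidation and PPAR target genes had 26 of 33 higher and a median of 0.15 (adjusted p = 0.0108, and adjusted p = 0.427 with an estimated correlation). PR dry replicate 1, the bright array, carries most of the mitochondrial shift: the mean changed by -0.06 to 1.04 among animals, with the largest change in animal 1, and without that array the median was 0.12 (adjusted p = 2.83e-10), with ATP5ME at 0.28 and NDUFB2 at 0.22. The Cy3 mean of the mitochondrial list rose by 0.20 (SE 0.19, adjusted p = 0.0135) and that of the ribosomal list fell by 0.022 (SE 0.019, adjusted p = 8.1e-05), while Cy5 alone rose by 0.68 (SE 0.54) and 0.31 (SE 0.20). Without PR dry replicate 1 the ribosomal median was 0.12 and the fatty acid oxidation median 0.048, and the monocyte median was 0.24, with CTSS at 0.28. Monocyte genes had 20 of 23 higher and a median of 0.39 (adjusted p = 0.00258, adjusted p = 0.37 with an estimated correlation and 0.0289 by fry), with VCAN at 0.77 and CTSS at 0.63. Heat shock and chaperone genes had 27 of 34 higher and a median of 0.18 (adjusted p = 0.0328, and adjusted p = 0.836 with an estimated correlation), with HSPD1 and CACYBP at 0.53 each and HSPA8 at 0.34, and without PR dry replicate 1 its median was 0.051 (adjusted p = 0.325), with HSPD1 at 0.24, CACYBP at 0.23 and HSPA8 at 0.11.

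Lower in PR lactation were gamma delta T cell genes, with 7 of 8 members lower and a median of -0.17 (adjusted p = 0.00535, and adjusted p = 0.427 with an estimated correlation). In that list the scavenger receptors CD163L1 and WC1.3 had -0.72 and -0.50, and TRGC6 had -0.18. Over the alternatives CD163L1 ran from -1.14 to -0.29, WC1.3 from -1.72 to -0.29 and TRGC6 from -1.07 to -0.024. Erythroid genes had 16 of 26 lower and a median of -0.068 (adjusted p = 0.0328, and adjusted p = 0.836 with an estimated correlation), with FECH at -0.16, AHSP at -0.13 and SPTB at 0.30. For SPTB, PR dry replicate 1 lay at -0.90 against -0.11 for the nearest PR dry array. Eosinophil, basophil and mast cell genes had 10 of 13 lower and a median of -0.056 (adjusted p = 0.0438, and adjusted p = 0.427 with an estimated correlation), which the animal block moved to an adjusted p = 0.0932. PRG3 had -0.25, CRLF2 -0.13 and FCER1A 0.38. With slide as a fixed block, the monocyte (adjusted p = 0.113), fatty acid oxidation (0.0833), gamma delta T cell (0.382) and eosinophil (0.113) calls ended. Without PR dry replicate 1 the erythroid (adjusted p = 0.443) and eosinophil (0.183) calls ended, and the gamma delta T cell median was -0.31. The other 22 lists did not pass, and for T cell, NK and cytotoxic cell, MHC class II, MHC class I, cytokine, milk protein, prolactin axis and vitamin D genes the median, the mean and the test did not all have the same sign. The exact permutation test gave p = 0.0286 for the fatty acid oxidation mean and p = 0.0857 for the mitochondrial mean, and 0.429 for both after adjustment over the lists, and the exact sign flips p = 0.125 and p = 0.25.

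In deer, a transcript of the beta globin region fell at peak lactation. The probe A_73_P075736, which the files give as an uncharacterised protein, lies on chromosome 15 at 49039613 to 49039672 (UMD 3.1), between probes of the globin genes HBE2, 9735 bases away, and HBB, 16577 bases away. Its log2 ratio went from 4.67 ± 1.20 to 1.27 ± 1.12 (SD, n = 4 each) and fell by 3.40 (SE 0.45, limma adjusted p = 0.00723), in 4 of 4 animals. The probe was at 0.73 and 0.18 on lactation replicates 2 and 4, the arrays of narrow spread, and at 2.77 and 1.38 on replicates 1 and 3. On the dry arrays it lay between 3.62 and 6.36. The second probe that passed, A_73_107213 on chromosome 7 at 45230228 to 45230287, has no gene name and lies within the span of a probe of SBNO2, from 45222225 to 45233247. It fell by 0.78 (SE 0.12, adjusted p = 0.0476), and the animal block gave an adjusted p = 0.27 for it against 0.000297 for the globin region probe. Of 33389 probes tested, these 2 passed and 3027 had an unadjusted p under 0.05, while the analysis of variance with Tukey's comparison gave 366. Without deer lactation replicate 2 or without replicate 4 limma called 0 probes, and without replicate 3 it called 63.

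Genes of cell division led the ranking in deer without passing 1 by 1. TPX2, which builds the mitotic spindle, was nearest to the threshold, at 0.55 (SE 0.09, adjusted p = 0.0889) and higher in 4 of 4 animals. MCM4, part of the replicative helicase, had 0.69 (SE 0.14), KNSTRN, a kinetochore protein, 0.68 (SE 0.13), and CDCA3, which triggers entry into mitosis, 0.86 (SE 0.17). RMI2, of DNA repair, had 0.70, TRPT1 0.62, ELP5 0.47 (-0.10 with scale normalization) and CDYL2 0.39. On the lower side were MLF1 at -0.87, ASGR1, the asialoglycoprotein receptor subunit, at -0.63, the origin recognition protein ORC5 at -0.63, MPDZ at -0.51, the cannabinoid receptor CNR1 at -0.49 (0.098 with the processed signals), SBNO1 at -0.46, MAMDC4 at -0.36 and MOS at -0.28. Of these 16 ranked genes, 11 lay nearer to 0 on both lactation arrays of narrow spread than on the other lactation arrays, and without deer lactation replicate 2 TRPT1 differed by 0.42, ASGR1 by -0.46 and CNR1 by -0.33. Of the genes seen above background in 1 deer state alone, the Cy5 signal of SCTR was at least 1.16-fold higher in the dry period (log2 ratio lower in lactation by 0.24, adjusted p = 0.453) and that of ARSD at least 1.14-fold higher in lactation (log2 ratio higher by 0.13, adjusted p = 0.707). For IL17RE the Cy5 signal was at least 1.23-fold higher in the dry period, but its log2 ratio was higher in lactation by 0.24 (adjusted p = 0.735), so its direction is not settled.

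As groups, cell cycle genes rose in deer at peak lactation, with 46 of 49 members higher, a median of 0.35 and a camera adjusted p = 2.42e-18. The call had an adjusted p = 0.0962 with an estimated correlation and 0.00485 by fry, and 26 members passed when adjusted over the list alone, among them TPX2, MCM4 and the mitotic kinase PLK1 (0.53, or -0.025 with scale normalization between arrays). Cytosolic ribosomal protein genes had 74 of 79 higher and a median of 0.17 (adjusted p = 1.33e-05, and adjusted p = 0.80 with an estimated correlation), with RPL38 at 0.38, RPS2 at 0.35 (-0.30 with scale normalization) and RPLP0 at 0.28. The reference moved in this list, with a Cy3 mean lower in lactation by 0.059 (SE 0.014, adjusted p = 1.12e-08), and the Cy5 channel alone rose by 0.050 (SE 0.078), against 0.16 (SE 0.10) for the mean log2 ratio. Mitochondrial respiratory chain genes had 74 of 78 higher and a median of 0.15 (adjusted p = 0.00116, and adjusted p = 0.80 with an estimated correlation), with NDUFB4 at 0.84 and NDUFB1 at 0.29 (-0.65 and -0.013 with scale normalization) and, against the list, ATP5F1E at -0.57. NDUFB4 was at -2.12 and -3.26 on lactation replicates 2 and 4, the arrays of narrow spread, against -4.20 and -4.34 on the other two, and its difference was 0.39 without replicate 2. The Cy3 mean of this list fell by 0.031 (SE 0.011) and Cy5 alone rose by 0.084 (SE 0.072), against 0.17 (SE 0.07) for the log2 ratio. Neutrophil and granule genes had 23 of 30 lower and a median of -0.23 (adjusted p = 0.00116, and adjusted p = 0.80 with an estimated correlation), with the cathelicidin CATHL2 at -1.44, S100A9 at -1.01 and S100A12 at -0.94. Over the alternatives CATHL2 ran from -1.96 to -0.38, S100A9 from -1.865 to -0.64 and S100A12 from -2.01 to -0.50. Erythroid genes had 21 of 26 lower, a median of -0.094 and a mean of -0.40 (adjusted p = 0.0027, and adjusted p = 0.80 with an estimated correlation). The globin genes HBG (-3.38, SE 1.07) and HBB (-3.02, SE 0.98) made up most of that mean, and the carbonic anhydrase CA1 had 0.31 (-0.024 with slide as a fixed block). For CA1, deer dry replicate 2 lay at -0.74 against 0.23 for the nearest deer dry array. Milk protein and mammary genes had 11 of 16 lower and a median of -0.060 (adjusted p = 0.0344, and adjusted p = 0.224 with an estimated correlation), with BTN1A1, a coat protein of milk fat droplets, at -0.26 and GPAT4 at -0.69 (0.052 with scale normalization). GPAT4 counts as 2 of these 16 members, since it also stands in the list under its old symbol AGPAT6. The call ended in 13 of 26 alternatives, whose medians ran from -0.22 to -0.017.

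With slide as a fixed block, only the cell cycle (median 0.27, adjusted p = 1.42e-08) and mitochondrial (median 0.13, adjusted p = 0.00382) calls remained among these 6 deer lists. That block reads the deer states within slide J alone, which holds 1 dry and 2 lactation arrays. The ribosomal median went from 0.17 to 0.044 (adjusted p = 0.514), and the neutrophil (0.161), erythroid (0.117) and milk protein (0.787) lists no longer passed. The other 24 lists did not pass in deer, although the animal block gave an adjusted p = 0.0258 for interferon-stimulated genes (median 0.16). For eosinophil, MHC class II, complement, prolactin axis, glucocorticoid, vitamin D, fatty acid oxidation, immediate early and circadian clock genes the median, the mean and the test did not all have the same sign. The exact permutation test gave p = 0.0286 for the neutrophil, erythroid and cell cycle means, and 0.286 for each after adjustment, and the exact sign flips p = 0.125 for each.

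**Figure D2:**
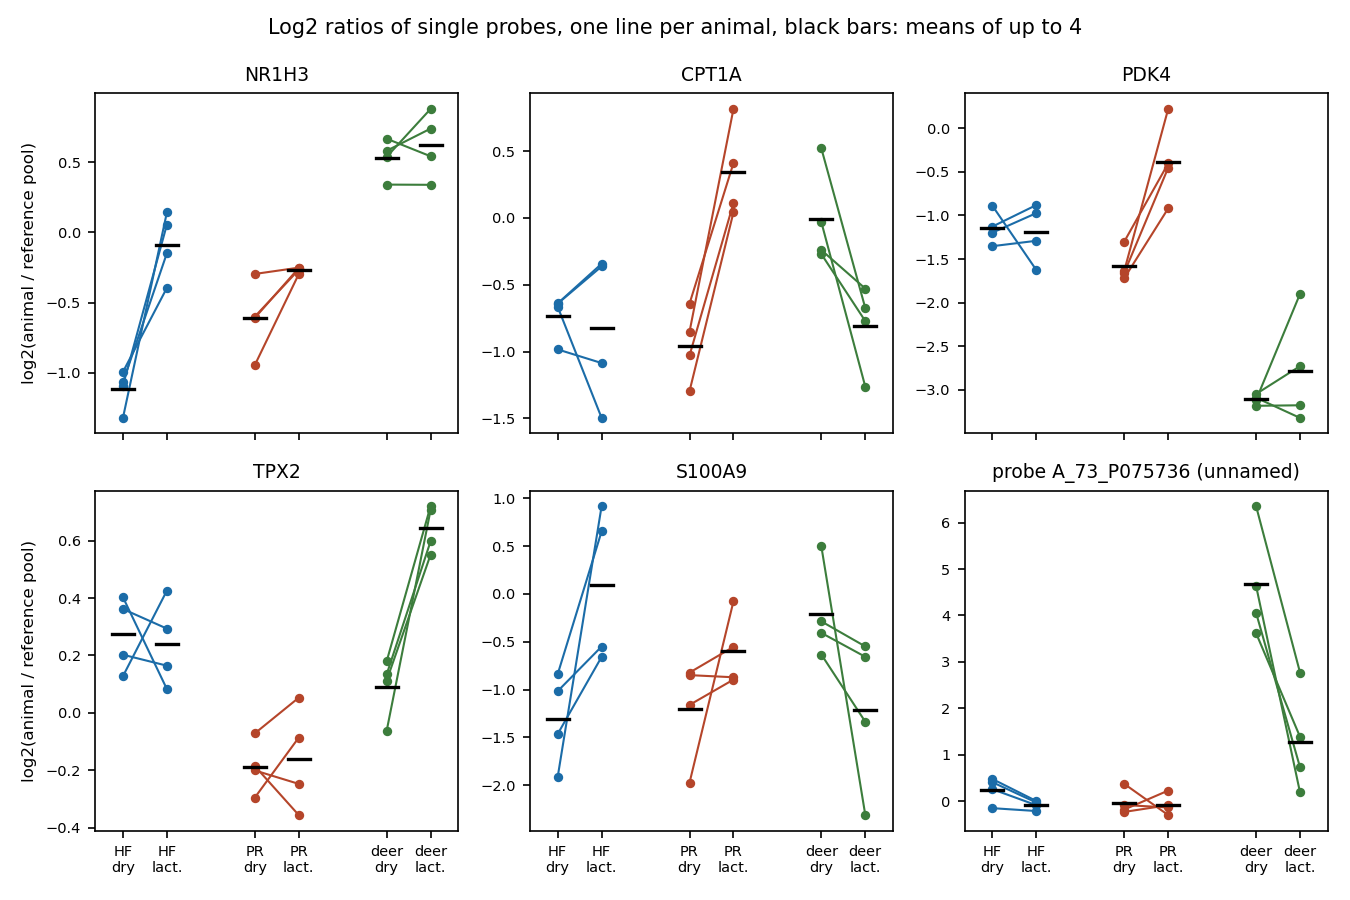
Log2 ratio to the common reference (vertical axes) of the brightest probe of 5 genes and of the deer globin region probe, with points for arrays joined within an animal from dry period to peak lactation and black bars for group means. NR1H3 is higher at peak lactation in 4 of 4 HF animals and the globin region probe lower in 4 of 4 deer, while CPT1A, PDK4, TPX2 and S100A9 did not pass the test.

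The size of the response to lactation was then compared between the breeds. For no probe did the HF and PR effects differ past the threshold in limma, with 0 of 32213 called and 987 at an unadjusted p under 0.05. The contrasts with the smallest p were OSCAR (1.39, SE 0.33), NR1H3 (0.69, SE 0.19) and LGALS9 (0.66, SE 0.20) toward HF, and CPT1A (-1.39, SE 0.34), SLC25A20 (-0.90, SE 0.21) and VAMP2 (-0.54, SE 0.15) toward PR, each with an adjusted p = 1.00. CPT1A was -0.73 ± 0.17 and -0.82 ± 0.57 in HF dry and lactation (SD, n = 4 each). As groups, ribosomal protein genes had the smallest p, with 0 of 79 members responding more in HF and a median difference of -0.38 (camera adjusted p = 1.11e-20, and adjusted p = 0.225 with an estimated correlation), followed by mitochondrial genes at -0.38 (adjusted p = 5.4e-11, and adjusted p = 0.54 with an estimated correlation). Without PR dry replicate 1 these differences were -0.24 and -0.11. Neutrophil genes responded more in HF, by 0.39 (adjusted p = 1.89e-08), as did immediate early genes, by 0.29, and acute phase genes, by 0.28, but without slides G and H these were 0.016, -0.026 and -0.010 and did not pass. Of the 15 lists that passed, none did with an estimated correlation, where the smallest adjusted p = 0.225, or by fry, where it was 0.679.

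Deer and cattle were compared in the same way, since a sequence mismatch that shifts both states alike cancels in a difference of responses. A mismatch that shrinks the deer response would not cancel, and this was not tested. No probe passed in limma, with 0 of 30600 called, 2623 at an unadjusted p under 0.05 and a smallest adjusted p of 0.127. TPX2 (0.55, SE 0.12), CDYL2 (0.41, SE 0.09) and TRPT1 (0.81, SE 0.18) leaned toward deer, and CPT1A (-1.41, SE 0.29), the metalloreductase STEAP4 (-1.62, SE 0.34) and FNDC3B (-0.95, SE 0.22) toward cattle, with adjusted p-values from 0.421 to 0.482. Myeloid lists differed between the deer and cattle responses by camera at its preset correlation, but only monocyte genes held with an estimated correlation. The deer states lie mostly on different slides, while each HF animal has both on 1 slide, so a slide effect is not excluded. Neutrophil genes differed by a median of -0.60, with 27 of 29 members lower and 8 of these passing over the list alone (camera adjusted p = 1.58e-09, and adjusted p = 0.271 with an estimated correlation), and by -0.225 without slides G and H. Monocyte genes differed by -0.46 (adjusted p = 3.45e-07), a call that held with an adjusted p = 0.0213 with an estimated correlation and 0.0181 by fry. Cell cycle genes differed by 0.28 (adjusted p = 1.25e-12, adjusted p = 0.172 with an estimated correlation and 0.0428 by fry) and B cell genes by 0.36 (adjusted p = 0.00175, and adjusted p = 0.486 with an estimated correlation).

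Between the breeds in the dry period, 885 of 32924 probes passed in limma, 780 higher in HF and 105 lower, from 633 named genes. Higher in HF were POLR3A, the catalytic subunit of RNA polymerase III, by 0.95 (SE 0.13, adjusted p = 0.00744), CNTROB by 0.71 (SE 0.10, adjusted p = 0.00744) and the centrosome scaffold CEP192 by 0.85 (SE 0.13, adjusted p = 0.0131). HERC2, a ubiquitin ligase, was higher by 0.81 with 3 of its 6 probes in that direction, EMC1, of the membrane protein insertase, by 0.62 and the growth kinase MTOR by 0.54 (adjusted p = 0.0147). Lower in HF were OAS1X, an interferon-induced antiviral enzyme, at -3.02 (SE 0.50, adjusted p = 0.0147), and SMAD5, a transducer of BMP signals, at -0.39 (SE 0.06, adjusted p = 0.0143). CYHR1 at -0.49, SGK3 and the tight junction protein CLDN5 at -0.45 each and the calcium-binding CABP1 at -0.42 also passed. The count rests on few arrays and on the slides: it was 1 without HF dry replicate 2, 8 without HF dry replicate 3, 9 without PR dry replicate 4, 52 without PR dry replicate 3, 205 without PR dry replicate 1 and 275 without HF dry replicate 4, and 513 without HF dry replicate 1. It was 4270 without PR dry replicate 2, the only PR array on an HF slide, and 2 with slide as a fixed block. With any 1 dry array of either breed left out, all 885 probes, which were chosen with all arrays present, kept their sign. Their median absolute difference was then 0.49 to 0.73, against 0.62 with all arrays, so the counts moved more than the differences did. Such a choice of probes favours a kept sign, so the signs are not independent evidence of a difference.

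Lists that passed between the breeds in the dry period were mitochondrial (median 0.42, adjusted p = 4.59e-09), ribosomal (0.36, adjusted p = 2.98e-07), cell cycle (0.34, adjusted p = 1.3e-06) and heat shock genes (0.30, adjusted p = 0.0223) on the HF side. Erythroid (-0.18, adjusted p = 0.00188), interferon-stimulated (-0.092, adjusted p = 0.0089) and acute phase genes (-0.16, adjusted p = 0.0135) passed on the PR side. All 7 had an adjusted p = 0.832 with an estimated correlation, and cell cycle genes had 0.0157 by fry. The bright array PR dry replicate 1 carries much of the first 2: without it the medians were 0.17 for mitochondrial, 0.19 for ribosomal, 0.30 for cell cycle and 0.15 for heat shock genes, and the heat shock (adjusted p = 0.0537) and acute phase (adjusted p = 0.173) calls ended. Without PR dry replicate 3 the interferon median was 0.014 (adjusted p = 0.273). The erythroid median was -0.070 without HF dry replicate 3 and -0.29 without HF dry replicate 1, and the interferon median -0.197 without HF dry replicate 3. Without HF dry replicate 2 the acute phase (camera adjusted p = 0.0754) and heat shock (0.0505) calls ended. At peak lactation limma called 0 of 32949 probes, with 4749 at an unadjusted p under 0.05, 967 by the analysis of variance with Tukey's comparison and a smallest adjusted p of 0.0547 for OAS1X (-3.25, SE 0.50). SMAD5 (-0.36), SBNO1 (-0.61), MTOR (0.47), SEC23B (0.39) and the kinase TEC (0.78) followed. Of the 885 dry-period probes, 867 (98.0%) had the same sign at peak lactation and 497 an unadjusted p under 0.05, while their median absolute difference was 0.33 against 0.62. The same animals, mostly on the same slides, stand in both comparisons, so agreement is expected from animal and slide, and over all 32395 probes tested in both 70.1% had the same sign. Cell cycle (0.21), immediate early (0.38), MHC class I (0.33), neutrophil (0.42) and cholesterol synthesis genes (0.17) were higher in HF at peak lactation and ribosomal genes lower (-0.075), and none of these 6 lists passed with an estimated correlation (adjusted p = 0.773).

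**Figure D3:**
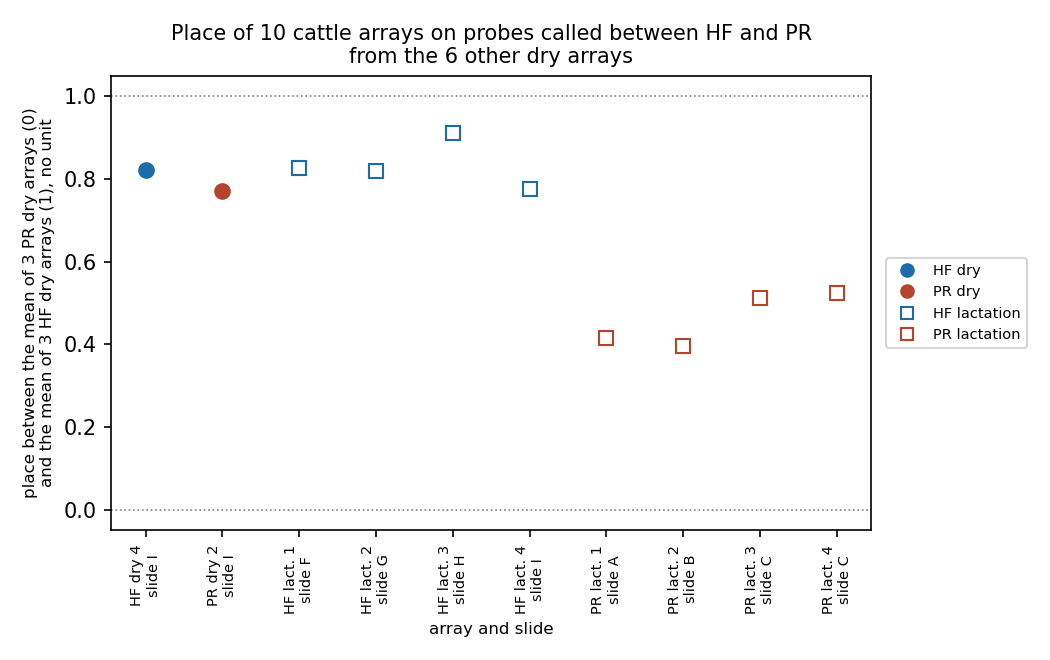
Place of 10 cattle arrays (vertical axis, no unit) between the mean of 3 PR dry arrays, at 0, and the mean of 3 HF dry arrays, at 1, over 3516 probes called between those 6 arrays. PR dry replicate 2, which shares slide I with HF arrays, lies at 0.77, the PR lactation arrays at 0.40 to 0.52 and the HF lactation arrays at 0.78 to 0.91.

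Deer and cattle differed in 56.7% of the probes tested in the dry period and 48.7% at peak lactation, on arrays whose probes were designed on cattle sequence. No deer array shares a slide or scan day with a cattle array, so species cannot be told apart from slide and scan day. On deer lactation replicates 2 and 4 the log2 ratios spread less (SD 0.52 and 0.66). Whether this lowered the share at peak lactation was not tested. In the dry period 19934 of 35175 probes passed in limma, 9228 higher and 10706 lower in deer, and at peak lactation 16690 of 34265, 7473 higher and 9217 lower. The balance of directions depends on the normalization, since median centring in place of loess called 14538 higher and 7020 lower in the dry period. Among the gene lists, glucocorticoid and steroid response genes were higher in deer in the dry period (median 0.31, adjusted p = 0.0333) and cholesterol synthesis genes lower (median -0.65, adjusted p = 0.0377), and both had an adjusted p = 0.932 with an estimated correlation. No list passed by camera at peak lactation, against 13 by fry, which tests whether a list moves without comparing it with other genes.

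The authors' deposited lists were read in the same model. In HF, 424 of 424 probes that could be fitted had the deposited direction and 3 passed here. In PR it was 153 of 155, with 0 passing, and in deer 375 of 421 (89.1%), with 2 passing. These lists were chosen on these samples, so their direction is not independent evidence. The HF and PR lists share 15 probes, against 1.58 expected if drawn at random from all 43653 probes. The HF and deer lists share 10 against 5.77, and the PR and deer lists 9 against 2.08. All 3 lists come from an analysis of variance on the same arrays, so overlap beyond random draws does not by itself show a shared response.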

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

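Apart from the tests of the Cy3 channel for gene lists and the difference within slide J, the tests in this part, the counts over other splits included, were set out after the results they bear on had been seen. For slide J, the demand that the difference exceed its bound by a standard error was added after its value was seen.

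Neutrophil and granule genes were higher in HF lactation by a mean of 0.69, with a spread between animals from 0.11 to 1.47. A shift of the reference channel is argued against, since the list's mean in Cy3 alone changed by 1e-04 (SE 0.041). With array position as a factor the rise was 0.63 (SE 0.44), and HF dry arrays all lie at position 1, so position cannot be told apart from state in HF. Fewer lymphocytes alone would raise all other cell types alike. Of the 10 pairs among neutrophil, monocyte, platelet, erythroid and eosinophil genes, monocyte and platelet genes moved furthest apart in standard errors, by 0.431 (SE 0.088). That leans against this, but a permutation of the cell types within animals gave p = 0.0687 for the largest of the 10 differences, which leaves it open. The neutrophil rise exceeded the erythroid by 0.55 (SE 0.30) and the platelet by 0.73 (SE 0.31). A shift in the blood cell mix with lactation may be part of the pattern, as the study's states allow, but cell counts were not analysed here.

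The 885 probes between HF and PR in the dry period are consistent with a slide effect in part. PR dry replicate 2, the only PR array on an HF slide, lay 0.772 of the way from the PR to the HF mean over 3516 probes called without it and without the HF dry array of its slide. The bright array PR dry replicate 1 bears on the count as well, which was 205 without it. All 885 probes kept their sign without that array, with a median absolute difference of 0.49 against 0.62. They were chosen with that array present, which favours a kept sign, so no conclusion follows from the signs. Over the 885 probes, Cy3 alone differed by a mean of 0.264 (SE 0.29) in the direction of the calls, against 0.64 (SE 0.15) for the log2 ratio, where a shift of the reference would need a difference against that direction, so the values argue against it as the whole cause. Over the same 3516 probes, the HF and PR dry arrays of slide I differed in the direction of the other arrays for 1965 (55.9%), by a median of 0.027 against 0.66. A breed difference stays open, since the pair within a slide is 1 array against 1.

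Cell cycle genes were higher in deer lactation by a mean of 0.35. The Cy3 channel changed by -0.019 (SE 0.0089) and the rise was at least 0.31 when any 1 deer array was left out, here deer dry replicate 4, so neither the reference nor 1 array accounts for it. Within slide J the rise was 0.27, with an SE of 0.088 taken from the spread within both deer groups over all their slides. The rise there rests on 1 dry and 2 lactation arrays, so slide and scan day cannot be told apart from state for the rest. More dividing cells in blood at peak lactation may lie behind the rise, a hypothesis without a test here.

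Whether other splits of the arrays give as many calls was counted for each comparison. In HF, 5 of 35 splits gave as many as the real 3 probes, with a highest other count of 10, so chance cannot be excluded; of the 8 splits that part all 4 animals, the real one alone called any. In PR the real count was 0, which every split reaches, so no conclusion follows (highest other 7). In deer, 15 of 35 gave as many as the real 2, with a highest other of 588. Splits that keep each animal's arrays together gave 84, 588 and 5 calls, and a split that parts 2 animals gave 226. What sets these counts was not tested. Among the 8 splits that part all deer, 2 gave as many and the highest other was 53. For the gene lists, 6 of 35 splits gave as many as the 17 in HF (median of the others 12, highest 19). In PR, 11 of 35 gave as many as the 8 (median 5.5, highest 12), and in deer 19 of 35 as many as the 6 (median 6, highest 14). Camera at its preset correlation thus called many lists in other splits too, and chance cannot be excluded for any of these 3 counts. Between HF and PR, 1 of 35 splits, the real one, gave 885 in the dry period, with a highest other of 4. That share, 0.0286, is the smallest that 35 splits allow, and several comparisons were counted. The real split stands out, but neither chance nor slide is excluded. At peak lactation the real count was 0, which every split reaches, so no conclusion follows (highest other 3). For the difference of the HF and PR effects and for deer against cattle effects the real counts were 0, which all of the 100 splits drawn reach. No conclusion follows from these (highest other 8 and 123). Deer against cattle levels gave 1 of 100 in each state, the smallest share that 100 draws allow. The real count was 19934 against a highest other of 12586 in the dry period, and 16690 against 10934 at peak lactation. These counts do not part species from slide.

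Single arrays lay far from the rest of their group in several values, judged by the gap to the nearest array over the group's range, where chance gives about 1 group in 20. Among named genes this was so in 13 of 331 groups (3.93%). For PR dry the gaps were 0.917 for OSCAR and 0.908 for SPTB, both from replicate 1, and 0.934 for CEP192 and 0.917 for FECH from replicate 2. For PR lactation the gap was 0.837 for ITGA10. For HF dry they were 0.955 for OAS1X and 0.927 for CPT1A, both from replicate 4, and 0.912 for PFKFB4 and 0.839 for IL1RN, both from replicate 3. For HF lactation they were 0.894 for GATA3 from replicate 3, and 0.856 for NLRC4 and 0.854 for OAS1X from replicate 4. In deer dry the gap of CA1 was 0.977, with replicate 2 at -0.74.

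Among list means, 8 of 62 groups (12.9%) had such an array. In HF lactation the gap was 0.854 for interferon-stimulated genes, 0.859 for NK and cytotoxic cell genes and 0.846 for acute phase genes, the last from replicate 3 at 1.14. In PR it was 0.973 for fatty acid oxidation genes in the dry period, from replicate 1, and 0.882 for ribosomal and 0.833 for heat shock genes in lactation. In deer lactation it was 0.888 for ribosomal and 0.934 for cell cycle genes. Among measures of the arrays, 5 of 24 groups had one: 0.976 for the median Cy5 and 0.977 for the median Cy3 intensity in PR dry, 0.922 for the median Cy3 in PR lactation, and 0.879 in HF dry and 0.937 in PR dry for the spread of log2 ratios.

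Responses to lactation differed between HF and PR for 15 lists by camera, and for none with an estimated correlation. Median differences, HF minus PR, were 0.39 for neutrophil, 0.29 for immediate early, 0.28 for acute phase, 0.13 for glucocorticoid, 0.12 for cytokine, 0.10 for erythroid and 0.087 for interferon-stimulated genes. They were 0.067 for prolactin axis, 0.055 for glycolysis, 0.045 for milk protein, 0.042 for monocyte, 0.034 for complement and 0.032 for pattern recognition receptor genes, and -0.38 for both mitochondrial and ribosomal genes. Without PR dry replicate 1 the last 2 were -0.11 and -0.24, and without slides G and H the neutrophil difference was 0.016, with 9 lists past the threshold.

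Between deer and the mean of cattle, 15 lists differed by camera, of which monocyte genes (-0.46) held with an estimated correlation. The other medians were -0.60 for neutrophil, -0.42 for acute phase, -0.27 for immediate early, -0.22 for glycolysis, -0.15 for complement, -0.12 for cytokine, -0.11 for glucocorticoid, -0.081 for fatty acid oxidation, -0.078 for pattern recognition receptor, -0.075 for erythroid and -0.073 for milk protein genes. They were 0.36 for B cell, 0.28 for cell cycle and 0.087 for ribosomal genes.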

How the results depend on the processing

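The models without PR dry replicate 1 or deer lactation replicate 2 for contrasts that lack those arrays, and those without slides G and H, were chosen after seeing the data. Of 341 counts under alternatives, 251 stayed within 1.5 times the count reported, many of them 0 where 0 was reported. Counts moved by more in 18 of 28 alternatives for HF, 19 of 27 for deer and 19 of 26 for HF against PR in the dry period. Of 4240 values for named genes, 10 changed sign, as did 5 of 823 list medians, and 148 more list calls ended. No alternative called a difference between the HF and PR effects. Signal over background limits what dim probes can show, and for changes below the threshold the cause was not tested.

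Calls of state contrasts moved as follows. For HF (3 probes) the count was 0 with median centring, with Cy5 alone, with slide as a fixed block, with array position and without slides G and H. It was 1 with HF arrays alone, with the animal block and with 1 probe per gene (fewer probes tested), 18 with scale normalization and 28 with array weights. For deer (2 probes) it was 1 with the processed signals, median centring, no background filter, array position and the trended robust variance, 0 with scale normalization, Cy5 alone, deer arrays alone, fixed slides and without slides G and H, and 4 with the animal block. Array weights, whose fit warned that its tolerance was not reached, gave 7474 in deer, and 3622 for deer against cattle effects (reported as 0). The analysis of variance with Tukey's comparison gave 360 in HF, 130 in PR and 366 in deer, or 348, 123 and 363 with its first p adjusted, and this lacks the adjustment over probes after the comparison.

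Between HF and PR in the dry period (885 probes) the count was 318 with the processed signals, 6115 with median centring, which put the median of all probes at 0.15 (0.0083 as reported), 1728 with scale normalization, 0 with Cy5 alone, 585 with no filter, 0 with only these groups, 2 with fixed slides, 5141 with array weights, 1757 and 1715 by the analysis of variance, and 2 without slides G and H. At peak lactation (0 probes) it was 1 with the processed signals or 1 probe per gene, 1872 with scale normalization, 249 with only these groups, 20 with the trended robust variance, 882 with array weights, 967 and 949 by the analysis of variance and 2 without slides G and H. Deer against cattle gave 12057 with scale normalization in the dry period, and 11982 and 10203 with 1 probe per gene, where fewer probes are tested. The share of deer list probes with the deposited sign was 100% with the processed signals.

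Lists past the threshold numbered 1 in HF, 0 in PR and 0 in deer with an estimated correlation, and 1 in each with fry. In PR they numbered 5 with Cy5 alone, 4 with fixed slides and 5 with the mean of all probes of a gene. Signs reversed for CNR1 in deer with the processed signals (0.098), for PLK1 (-0.025), RPS2 (-0.30), GPAT4 (0.052), NDUFB1 (-0.013), NDUFB4 (-0.65) and ELP5 (-0.10) in deer with scale normalization, for CA1 in deer with fixed slides (-0.024), for FCER1A in PR with array position (-0.10) and for ORM1 in HF without slides G and H (-0.020). With array position as a factor the medians of glycolysis (-0.022) and antioxidant genes (-0.032) in HF and of erythroid genes in PR (0.052) changed sign, and the last ranged from -0.18 to 0.073 when 1 array was left out.

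Leaving out 1 array at a time gave 1 to 7 probes in HF, 0 to 0 in PR, 0 to 63 in deer, 0 to 0 for the HF and PR effects, 0 to 10 for deer against cattle effects, 1 to 4270 for HF against PR in the dry period and 0 to 476 at peak lactation. Deer against cattle gave 18375 to 20793 in the dry period and 13700 to 17870 at peak lactation. The lists past the threshold ranged from 11 (without HF dry replicate 2) to 19 in HF, from 4 (without PR dry replicate 2) to 9 in PR and from 6 to 10 (without deer dry replicate 3) in deer. The 7, 476 and 17870 are without PR dry replicate 1. Slide as a fixed block could not be estimated for deer against cattle, and Tukey's comparison was not run for the differences of effects or for deer against cattle.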

Other observations

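The test of a shared pattern of the cattle breeds and the choice of the genes in this part came after results had been seen.

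Globin genes lay lower in deer at peak lactation than in the dry period. HBG was between -2.38 and 0.92 on the 4 deer dry arrays and between -4.86 and -3.40 at peak lactation, and HBB between -2.37 and 0.57 and between -4.49 and -3.38. These 2 were picked for their separation, and neither passed in limma (adjusted p = 0.466 for both). HBA had -1.59 (SE 0.96) and ALAS2, the first enzyme of haem synthesis in red cell precursors, -1.16 (SE 0.65), while AHSP had -0.04, KLF1 0.09 and TFRC -0.06. Globin values also spread widely in cattle, with HBG from -2.81 to 2.74 over the 16 cattle arrays, whereas the globin region probe that fell in deer lay between -0.30 and 0.47 in cattle.

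OAS1X separated HF animal 4 from the other HF animals in both states. Its log2 ratio was 1.02 in that animal in the dry period and higher still in lactation, against -1.23 to -0.79 in the other HF arrays and 1.38 to 3.29 in PR. PR dry replicate 2, which lay near HF over the probes called between the breeds, had 2.44 for OAS1X and the lactation array of the same animal 2.45.

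Response patterns were compared across probes, which are not independent replicates. The correlation of the state effects was 0.273 between HF and PR, -0.132 between HF and deer and 0.204 between PR and deer over 30600 probes. A response shared by the cattle breeds beyond chance is a hypothesis that may be put to test by swapping states within animals. Over 31733 probes the correlation was 0.277, and 6 of 100 draws, the real one included, gave as high a value, with a highest other of 0.302, so chance is not excluded. The authors' HF list had the HF direction in PR for 83.5% of probes and in deer for 52.6%, the PR list its direction in HF for 76.1% and in deer for 67.1%, and the deer list its direction in HF for 43.2% and in PR for 65.6%. Over all 30600 probes the signs agreed for 55.8% between HF and PR, 45.4% between HF and deer and 58.5% between PR and deer.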
